A study of Homo sapiens with 6 samples.

How the data were processed

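Total RNA of 6 OVCAR8 samples, 3 transfected with siControl and 3 with siHSD17B14 for 48 hours, was converted to biotin-labelled cDNA and hybridised to Clariom S human arrays, per the labels' protocols. The cells were transfected with Lipofectamine RNAiMAX, and whether the siRNA was a single sequence or a pool is not given in the sources used here. The deposited log2 values are the output of RMA, made with Transcriptome Analysis Console 4.0, per the submitters' processing notes. RMA corrects background, quantile normalizes and summarises probes to one log2 value per probe set; the base of the logarithm is taken from that method, since no header names it. The table gives 2 decimals and runs from 1.80 to 18.50. A total of 144 probe sets exceed 16 on at least 1 array, above the log2 limit of a 16-bit scan, so the scale may be stretched and folds are those of the deposited scale. Scanner files and detection p-values were not used here, so signal over background was judged from olfactory receptor probe sets.

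Samples were grouped by their titles, and each table column was matched to 1 sample by its name. Probe sets were named through the platform annotation, in which 17709 of 21448 have 1 gene symbol, 0 have several and 3739 are not listed and so are unnamed here. All 17709 symbols matched RefSeq's human gene table (assembly GRCh38.p14) through their Entrez gene numbers, and 0 differed. The build used by the authors is not given in the sources used here, and no coordinates are printed. No array control probe sets were found in the table by name.

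The table was analysed in R 4.3.3 with limma 3.58.1. A linear model with one mean per group was fitted to all 21448 probe sets without a filter, followed by eBayes with no intensity trend. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets, with a call at an adjusted p under 0.05. The prior degrees of freedom were 6.08 and the median residual SD was 0.215. Levels are given as mean ± SD of 3 arrays and differences with limma's moderated SE. HSD17B14 was also tested by an exact permutation of the 6 values.

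The comparison, its tests, the other settings to try, 36 gene lists and the rule for named genes were fixed before the data were examined. Named genes were HSD17B14, the 12 largest rises and 12 largest falls among called probe sets with 1 symbol whose groups do not overlap, up to 4 members with the smallest p of each list described, and the members of the 17beta-hydroxysteroid dehydrogenase family. ESR1, and gene symbols named outside this rule in the closing paragraphs, were chosen after their values were seen. Lists were tested with camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene (the one with the highest mean; 17687 genes), and adjusted over the 36 lists. Camera was repeated with the correlation estimated per list, and fry was run as another set test. List tests covered measured members only. A total of 133 listed symbols were not measured, and these can include older and newer names of one gene. Measured were 15 of 32 listed symbols for replication-dependent histones and 36 of 58 for cytosolic ribosomal proteins.

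The fit was tested on simulated data for 21448 probe sets in 3 arrays against 3. It recovered 60% of 100 probe sets changed by 1 on the log2 scale and 99% of 100 changed by 2, with 11 false calls among 170. In simulated independent values of 17687 genes, 0 of 36 lists passed camera with no change. A list lowered by 0.3 then passed with the preset correlation (adjusted p = 2.0e-05) but not with an estimated one (adjusted p = 0.199). Because the simulated genes were independent, these runs cannot show how often lists of correlated genes pass with no change.

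Alternatives were centring arrays on a common median, a second quantile normalization, filters at the 25th and 50th percentile of mean signal, 1-symbol probe sets alone, an intensity trend with robust variances, array weights, the replicate number as a block, leaving out each array in turn, other thresholds and other forms of the list test. Removal of a trend with local gene density was added after seeing the data.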

Results

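Gene expression was measured in OVCAR8, a cell line from a human high-grade serous ovarian carcinoma, 48 hours after transfection with a control short interfering RNA (siControl) or with one directed against HSD17B14 (siHSD17B14). Total RNA of 3 samples per group was hybridised to Clariom S human arrays, 1 array per sample. The deposited table held 21448 probe sets on a log2 scale, of which 17709 were paired with 1 gene symbol and 3739 with none in the annotation used here. Median log2 levels of the siControl arrays were 5.91, 5.87 and 5.85, and those of the siHSD17B14 arrays were 5.77, 5.89 and 5.82. Pearson correlations over all probe sets, which are not independent replicates, ran from 0.993 to 0.995 between arrays of one group and from 0.992 to 0.993 between arrays of different groups. The first principal component held 30.2% of the variance and separated the groups. The labels do not state that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

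The comparison asks how the transcriptome of these carcinoma cells differs after transfection with an siRNA against HSD17B14, a member of the 17beta-hydroxysteroid dehydrogenase family, whose enzymes interconvert the 17-keto and 17-hydroxy forms of steroids. The targeted gene itself (probe set TC1900011099.hg.1) had log2 levels of 3.94, 4.60 and 4.53 on the siControl arrays and of 2.99, 3.54 and 2.80 on the siHSD17B14 arrays. Its mean was 4.36 ± 0.36 (SD, n = 3) in the control and 3.11 ± 0.38 (SD, n = 3) after siHSD17B14. All 3 siHSD17B14 values lay below all 3 siControl values. The log2 difference of -1.25 ± 0.24 (SE) did not pass limma's test, with an adjusted p of 0.063 over all probe sets. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 arrays against 3 allow. Signal was near background, so no fold is given and the arrays check the silencing only weakly: all 6 values lay below 4.61, the 95th percentile of 348 probe sets for olfactory receptors, genes of the nasal epithelium whose median was 3.13. The call depended on the model, since the gene passed when 1-symbol probe sets alone were tested (adjusted p = 0.0452), with an intensity trend and robust variances (adjusted p = 0.0155) and with array weights (adjusted p = 0.0456), within a range of 0.0155 to 0.272 over 13 alternatives.

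After siHSD17B14, 25 probe sets were higher and 46 were lower, by 1.79-fold to 3.92-fold. The largest rise was that of AOX1, an aldehyde oxidase, which rose 3.92-fold from a log2 level of 6.03 ± 0.42 (SD, n = 3), a log2 change of 1.97 ± 0.21 (SE; limma adjusted p = 0.0132). The largest fall was that of ITGA3, the alpha-3 integrin subunit of a laminin receptor, from 12.45 ± 0.15 to 10.60 ± 0.09 (SD, n = 3), a 3.62-fold fall (limma adjusted p = 0.00447). The secreted collagenase MMP1 rose 2.51-fold to a log2 level of 15.62 ± 0.14, and TGM2, a protein-crosslinking transglutaminase, fell 3.22-fold from 13.31 ± 0.24 (SD, n = 3). All 71 probe sets had groups that did not overlap, and 45 of them differed by at least 2-fold.

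**Figure D1:**
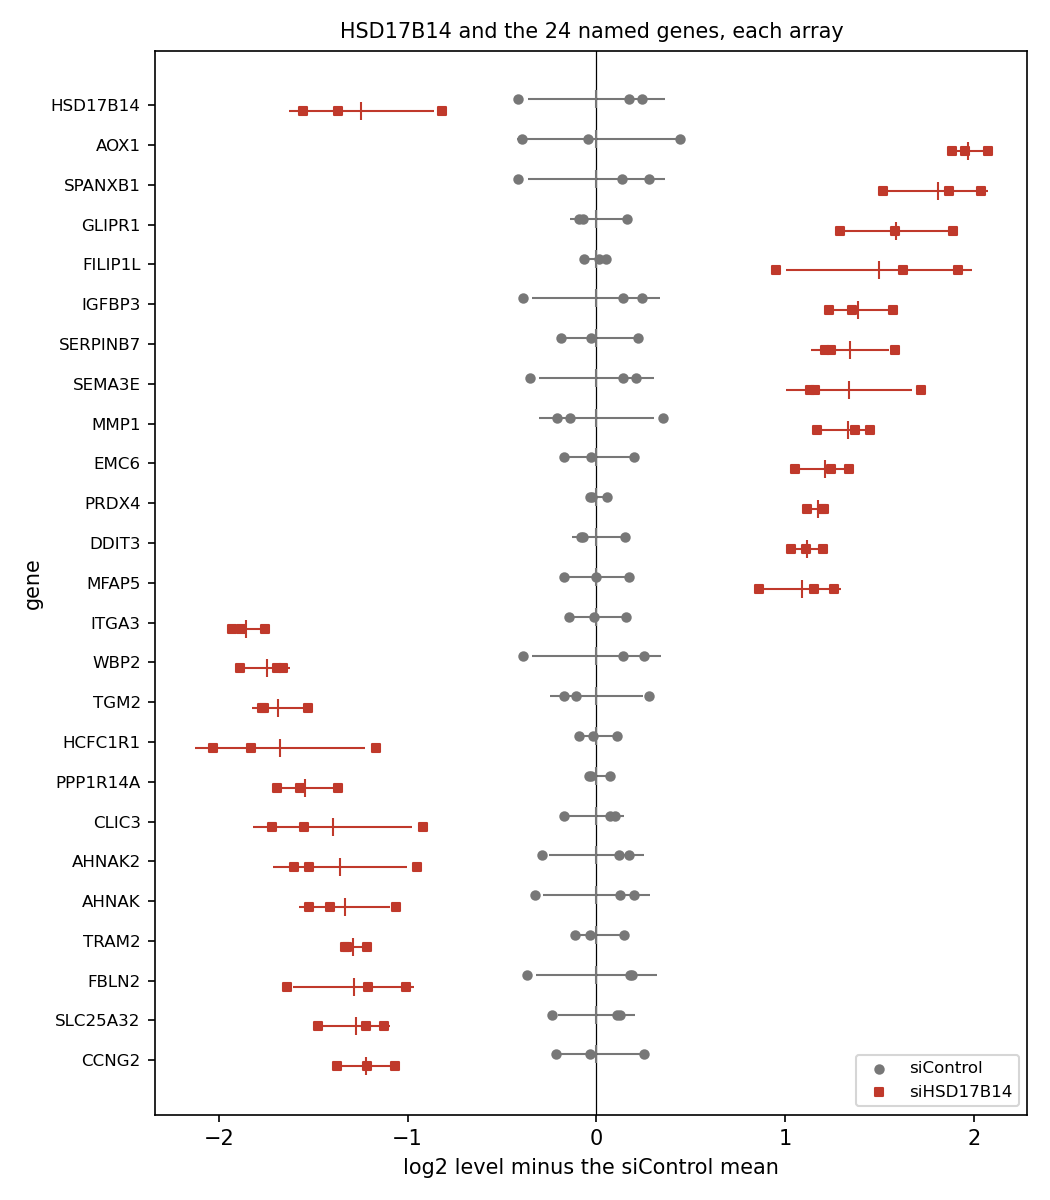
Log2 level of HSD17B14 and of the 12 largest rises and 12 largest falls on each array, minus the gene's siControl mean (x axis, log2 units), with genes on the y axis. Grey circles are siControl arrays, red squares are siHSD17B14 arrays, vertical ticks are group means and horizontal lines are ± 1 SD (n = 3); the groups do not overlap for any gene shown, and HSD17B14 (adjusted p = 0.063) is the only one of them that did not pass limma's test.

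Several of the 12 largest rises encode secreted proteins. Besides MMP1, these were IGFBP3, which binds insulin-like growth factors and rose 2.61-fold, the semaphorin SEMA3E, which rose 2.53-fold, and MFAP5, a microfibril-associated glycoprotein, which rose 2.13-fold. The peroxiredoxin PRDX4 had a log2 change of 1.17 ± 0.14 (SE), and the membrane protein complex subunit EMC6 one of 1.21 ± 0.16 (SE). DDIT3, the stress-induced transcription factor also called CHOP, rose 2.16-fold from 6.36 ± 0.13 (SD, n = 3). The remaining rises were GLIPR1 (3.00-fold), FILIP1L (2.82-fold), the serine protease inhibitor SERPINB7 (2.54-fold) and SPANXB1 (3.50-fold). SPANXB1 belongs to a family of near-identical genes on the X chromosome that is normally expressed in testis, so its probe set may bind transcripts of other copies. The grouping of secreted proteins follows their known function and was not tested for enrichment.

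Among the 12 largest falls were the scaffold proteins AHNAK and AHNAK2, which fell 2.52-fold and 2.56-fold. FBLN2, which encodes the extracellular matrix protein fibulin-2, fell 2.44-fold. PPP1R14A, an inhibitor of myosin phosphatase, fell 2.91-fold with little spread, from 13.24 ± 0.06 to 11.70 ± 0.16 (SD, n = 3). TRAM2, which takes part in protein translocation into the endoplasmic reticulum, fell 2.45-fold, and the mitochondrial folate and flavin carrier SLC25A32 fell 2.42-fold. The transcriptional coactivator WBP2 fell 3.36-fold, HCFC1R1 fell 3.20-fold, the chloride channel family member CLIC3 fell 2.63-fold and the atypical cyclin CCNG2 fell 2.33-fold. CCNG2 held the last of the 12 places in a tie with EPHA2, each with a log2 change of -1.22. Adjusted p-values of the 12 named rises and 12 named falls in limma ran from 0.00447 to 0.0459, and 7 of the 71 probe sets have no gene symbol here.

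The number of calls rested on all 6 arrays. Without siControl 2 no probe set passed limma's test (0 calls, lowest adjusted p = 0.0617, with 1943 at an unadjusted p under 0.05), and 1 passed without siControl 3, 1 without siHSD17B14 3, 5 without siHSD17B14 2, 6 without siControl 1 and 11 without siHSD17B14 1. Centring each array on a common median gave 51 higher and 44 lower, so the balance between rises and falls depends on the scaling.

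Of 36 gene lists, 6 passed limma's camera, a test of a list against all other genes, and all 6 were lower after siHSD17B14. No list passed when the correlation between genes was estimated from the arrays. That form of camera also missed a list lowered by 0.3 in simulated independent genes (adjusted p = 0.199). Its failure alone therefore cannot decide whether shifts of the size seen here are real. Fry, the other set test, passed 0 of the 36 lists too, with adjusted p-values from 0.079 to 0.353 for these 6. Fry was not run on the simulated values, so the simulation does not account for its result. Of the 831 genes on any list, 9 passed limma's test, against 64 of all 17709 probe sets with 1 gene symbol.

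Genes of cholesterol synthesis, targets of the transcription factor SREBP2, had a median log2 change of -0.32, with 16 of 19 measured members below 0. Camera gave an adjusted p of 3.1e-04, against an adjusted p = 0.712 with an estimated correlation. No member passed limma's test, over all probe sets or adjusted over the list alone (0 of 19 each). The reductase DHCR7 had a log2 change of -0.57, the factor SREBF2 itself of -0.48, the synthase LSS of -0.48 and the kinase MVK of -0.37.

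Fatty acid synthesis and desaturation genes had a median of -0.27, with 13 of 15 members below 0 (camera adjusted p = 0.00141, and adjusted p = 0.687 with an estimated correlation). None passed over all probe sets, while 4 lower and 1 higher passed when adjusted over the list alone. The elongase ELOVL5 had a log2 change of -0.79, the desaturase FADS2 of -0.82 and the synthase FASN of -0.56. The malic enzyme ME1, which supplies NADPH, went the other way, with a log2 change of 0.77.

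Hypoxia and glycolysis genes had a median of -0.24, with 26 of 33 members below 0 (camera adjusted p = 0.00141, and adjusted p = 0.712 with an estimated correlation). The angiogenic growth factor VEGFA fell 1.86-fold, from 9.11 ± 0.10 to 8.21 ± 0.08 (SD, n = 3; limma adjusted p = 0.0413), and the other 32 members did not pass. Adjusted over the list alone, 3 members were lower and 1 was higher. Log2 changes were -0.69 for the hexokinase HK1, -0.62 for the phosphoglycerate kinase PGK1 and 0.60 for the glucose transporter SLC2A3.

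ERK feedback and immediate early genes had a median of -0.17, with 20 of 25 members below 0 (camera adjusted p = 0.00141, and adjusted p = 0.687 with an estimated correlation). The median was -0.27 among the probe sets above the 50th percentile of signal. It was -0.12 with arrays centred on a common median and -0.15 after a second quantile normalization. The receptor tyrosine kinase EPHA2 fell 2.33-fold, from 9.68 ± 0.14 to 8.46 ± 0.09 (SD, n = 3; limma adjusted p = 0.0184). Cyclin D1 (CCND1) fell 1.85-fold, from 14.41 ± 0.07 to 13.52 ± 0.15 (SD, n = 3; limma adjusted p = 0.0459). The other 23 members did not pass, among them the feedback inhibitor SPRY4, with a log2 change of -0.80, and DUSP4, whose siHSD17B14 mean of 3.90 lay below the 95th percentile of the olfactory receptor probe sets. Adjusted over the list alone, 4 members were lower and 0 higher.

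Oestrogen receptor target genes had a median of -0.20, with 17 of 28 members below 0 (camera adjusted p = 0.0438, and adjusted p = 0.687 with an estimated correlation). CCND1, shared with the ERK list, was the one member called lower over all probe sets, and the other 27 did not pass. Adjusted over the list alone, 3 members were lower and 0 higher. Log2 changes were -0.98 for the progesterone receptor gene PGR and -0.70 for the secreted glycoprotein gene STC2, while MYB, with a mean of 5.06 in the control, was below that olfactory receptor mark after siHSD17B14. Both group means of 6 members lay below the mark, including those of the receptor gene ESR1 itself (3.38 and 3.42). The list passed in 1 of 6 fits that left out 1 array, the one without siControl 1, and had adjusted p-values from 0.0552 to 0.0844 without each of the others, with a median of -0.085 without siHSD17B14 3. It was also lost with a second quantile normalization (adjusted p = 0.0522), with ranks in place of values (adjusted p = 0.143) and among the probe sets above the 50th percentile (adjusted p = 0.175).

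G2/M and mitosis genes had a median of -0.18, with 35 of 45 members below 0 (camera adjusted p = 0.0243, and adjusted p = 0.712 with an estimated correlation). No member passed over all probe sets or adjusted over the list alone (0 of 45 each). The groups overlapped in list mean: relative to the mean of all 6 arrays, siHSD17B14 2 had 0.083, above siControl 1 (0.075) and siControl 3 (0.043). Log2 changes were -0.59 for ECT2, -0.42 for the centromeric histone CENPA, -0.38 for RACGAP1 and 0.45 for MYBL2. The call was lost without siControl 2 (adjusted p = 0.0800), without siHSD17B14 3 (adjusted p = 0.0552) and without siHSD17B14 1, where the median was -0.07 (adjusted p = 0.245). It was also lost among the probe sets above the 50th percentile (adjusted p = 0.0684).

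**Figure D2:**
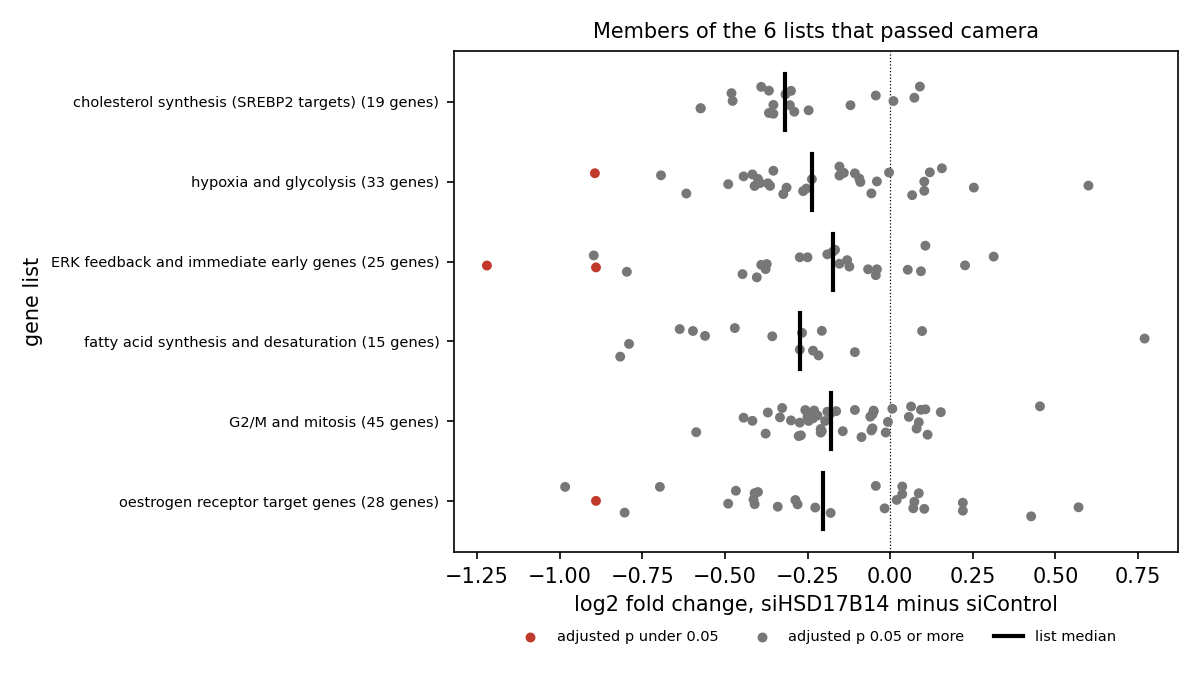
Log2 fold change of each measured member (points, x axis, siHSD17B14 minus siControl) of the 6 gene lists that passed camera (y axis), with list medians as black bars and members with a limma adjusted p under 0.05 in red. Medians lie between -0.32 and -0.17, and the red points are VEGFA, EPHA2 and CCND1, the last of these in both lists that hold it.

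The other 30 lists did not pass camera, with adjusted p-values from 0.121 to 0.994. The 17beta-hydroxysteroid dehydrogenase family, with the targeted HSD17B14 itself included, had a median log2 change of -0.26 over 12 measured members (adjusted p = 0.190). HSD17B7 is shared with the cholesterol synthesis list and HSD17B12 with the fatty acid list. None of the family's members passed over all probe sets, and HSD17B14 alone did when adjusted over the list alone (limma adjusted p = 0.00409). Log2 changes were -0.40 for AKR1C3, -0.33 for HSD17B13, -0.32 for HSD17B7, -0.31 for HSD17B4, -0.27 for HSD17B12, -0.25 for HSD17B2, -0.14 for HSD17B6 and -0.08 for HSD17B3. HSD17B13 and HSD17B3 were below the olfactory receptor mark in both groups. Log2 changes were 0.19 for HSD17B11, 0.21 for HSD17B10 and 0.26 for HSD17B1. The wider list of steroid hormone synthesis and conversion had a median of 0.11 (adjusted p = 0.264). Of its 22 members, 12 lay below the olfactory receptor mark in both group means.

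Single members of lists that did not pass were called over all probe sets. The collagen gene COL6A1 fell 2.26-fold (limma adjusted p = 0.0413) among mesenchymal and EMT genes (list adjusted p = 0.201), and TP53INP1 fell 2.23-fold (limma adjusted p = 0.0383) among p53 targets (list adjusted p = 0.415). The siHSD17B14 mean of TP53INP1, 4.18, lay below the olfactory receptor mark, so its fold rests on signal near background. DDIT3 was the one member of the ATF4 and amino acid stress list called higher over all probe sets (list adjusted p = 0.980). Adjusted over that list alone, 3 members were lower and 1 was higher. IGFBP3 was the one called higher among YAP/TAZ targets (list adjusted p = 0.733). NOLC1, at 1.79-fold, was the one called higher among MYC targets and ribosome biogenesis (list adjusted p = 0.312). CCND1 was the one member of the Wnt/beta-catenin targets called lower (list adjusted p = 0.470), a list with 11 of 20 members below the olfactory receptor mark in both group means.

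Markers of other cell types were measured as lists too. Mesothelial markers had a median log2 change of -0.15 (adjusted p = 0.121), immune markers of -0.10 (adjusted p = 0.227), fibroblast markers of -0.13 (adjusted p = 0.486) and endothelial markers of -0.02 (adjusted p = 0.980). Many lay below the olfactory receptor mark in both group means: 5 of 9 mesothelial, 12 of 18 immune, 6 of 12 fibroblast and 6 of 10 endothelial markers. The mesothelial list passed, lower, above the 25th percentile of signal (median -0.34, adjusted p = 0.0481) and without siControl 3 (median -0.315, adjusted p = 0.0443), but not over all genes with an estimated correlation (adjusted p = 0.712). Adjusted over the list alone, 1 mesothelial marker was lower (DES, log2 change -0.71, limma adjusted p = 0.00705), and 1 fibroblast marker was higher and 2 were lower. LUM rose (limma adjusted p = 0.0459) from a log2 level of 4.32 ± 0.07 (SD, n = 3), which lay near background, while COL1A1 and FBLN1, at higher levels, had log2 changes of -0.76 and -0.60 and did not pass over all probe sets. Müllerian and serous carcinoma markers did not pass as a list (adjusted p = 0.264, median 0.00), and 3 of 22 members, PAX8, FOLR1 and BCAM, were lower when adjusted over the list alone, with log2 changes of -0.81, -0.95 and -0.62. In both group means, 14 of the 22 members lay below the olfactory receptor mark. The list passed, lower, among probe sets above the 25th percentile of signal (median -0.39, adjusted p = 0.0221) and above the 50th (median -0.45, adjusted p = 0.0145), but not over all genes with an estimated correlation (adjusted p = 0.712). Epithelial genes had an adjusted p of 0.928.

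For growth and stress, adjusted p-values were 0.197 for G1/S and DNA replication, 0.264 for replication-dependent histones, 0.304 for apoptosis regulators, 0.588 for homologous recombination and Fanconi genes, 0.201 for the unfolded protein response and 0.980 for the cytosolic heat shock response. For metabolism and translation, they were 0.153 for oxidative phosphorylation (median 0.12), 0.632 for fatty acid oxidation, 0.319 for cytosolic ribosomal proteins, 0.856 for lysosome and autophagy and 0.994 for NRF2 targets. Interferon-stimulated genes, which foreign RNA can induce, had a median of 0.02 over 42 members (adjusted p = 0.980), and NF-kB targets had an adjusted p of 0.201. TGF-beta targets, housekeeping genes and genes of the short interfering RNA machinery each had an adjusted p of 0.980. Median, mean and camera direction differed in sign for 6 lists, none of which passed: lysosome and autophagy, short interfering RNA machinery, housekeeping genes, interferon-stimulated genes, the cytosolic heat shock response and NRF2 targets.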

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

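Removal of the gene density trend was chosen after seeing the data; the other settings were planned. All 71 called probe sets kept their sign and an unadjusted p under 0.05 in every setting that tested them (67 above the 50th percentile, 64 among 1-symbol probe sets or with the density trend removed). The 71, like the 24 named genes, were selected on these same arrays, so keeping their sign is not independent support. Counts of higher and lower probe sets moved with the setting: 51 higher after median centring, 45 and 71 above the 25th percentile, 117 and 202 above the 50th, 43 higher among 1-symbol probe sets, 137 and 219 with a trend and robust variances, and 72 lower with array weights. The filters and the 1-symbol setting test fewer probe sets; the cause was not tested for the others. With 1 array left out, fewer samples gave 0 to 4 higher and 0 to 7 lower. The 24 named genes kept their direction in all 359 fits and passed in 218; of those that did not, 139 left out an array or used the block, and the others were AHNAK2 (adjusted p = 0.0538) and FBLN2 (adjusted p = 0.0506) after a second quantile normalization. HSD17B14 passed at -1.25 among 1-symbol probe sets, at -1.25 with a trend and robust variances and at -1.33 with array weights; the cause was not tested for the last. It gave -1.46 to -1.09 with 1 array left out, and no value under the percentile filters, which remove it. With 1 array left out, uncalled HSD17B2 ranged from -0.66 to 0.065 (above 0 without siControl 1) and HSD17B3 from -0.17 to 0.018 (above 0 without siHSD17B14 1). Of 36 lists, 0 passed camera with an estimated correlation, 0 passed fry and 31 passed fry's mixed test, which asks another question, and 4 to 6 passed with 1 array left out. Besides Müllerian markers, lists gained were mesothelial markers above the 25th, with array weights and without siControl 3 (adjusted p = 0.0481, 0.0492 and 0.0443), and oxidative phosphorylation with a trend and without siHSD17B14 3 (0.0464 and 0.0398). The list test uses 1-symbol probe sets already. Shared replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.03, -0.03 and 0.06, and 3 of 6 arrays correlated best with their own number. With the number as a replicate block, 2 were higher and 5 lower, 5 lists passed and the oestrogen receptor list did not (adjusted p = 0.0522). Low signal limits HSD17B14 and other genes near background.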

Other observations

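The tests of gene density, of off-target action, of variation between arrays of one group and of gene families were chosen only after the results were seen. A scan of 98 families of at least 10 genes with a shared symbol stem, above the median signal, found 2 that passed camera, and 0 passed with an estimated correlation. Tetraspanins, membrane proteins that organise integrins and other receptors, were below 0 in 13 of 13 genes, with a median log2 change of -0.29 (limma camera adjusted p = 0.00278, and adjusted p = 0.999 with an estimated correlation). TSPAN1 was the one tetraspanin called, with a 2.12-fold fall (limma adjusted p = 0.0413). NBPF genes, near-identical copies whose probe sets may share transcripts, were below 0 in 10 of 10, with a median of -0.34 (adjusted p = 0.00278, and adjusted p = 0.999 with an estimated correlation). Zinc finger genes of the ZNF stem had a median of 0.08 over 285 genes and did not pass (adjusted p = 0.0559), but passed once the gene density trend was removed (adjusted p = 0.00194), as did the IFT (0.0252) and RPL (0.0288) stems, and none of these passed with an estimated correlation (adjusted p = 0.999).

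There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 71 calls, the highest of the others gave 0, and 1 split reached the real count, the real one itself. Each other split puts arrays of both groups on both sides, so a group difference adds to the spread within each side. Their 0 calls are therefore no baseline free of that difference. For gene lists the real split passed 6, the highest other passed 6, and 2 splits reached that number, the second being siControl 1 with siHSD17B14 1 and siHSD17B14 3 against the other arrays. Among the other splits the G2/M list passed in 2, with a lowest adjusted p of 0.00475 against 0.0243 in the real split, and the hypoxia and glycolysis list passed in 2, with a lowest of 0.0234 against 0.00141. The ERK and oestrogen receptor lists passed in 0 others (lowest adjusted p = 0.135 and 0.445), but another split gave the ERK list a median of larger size (0.187) than the real one (0.173).

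The cholesterol and fatty acid synthesis lists were lower by camera, but not with an estimated correlation (adjusted p = 0.712 and 0.687), and 0 members of either passed limma over all probe sets. Dependence on signal intensity is argued against, since both medians lay at or below percentile 0.04 of 10000 random lists matched on signal, as is a gene density trend, since at least 1.075 of each median was kept once it was removed. A single array is argued against too, since at least 0.9 of each median was kept in every fit that left out 1 array. Variation between arrays of one group remains open: list means of the groups did not overlap, but either list passed in 2 of 9 other splits, and the fatty acid list had a lower adjusted p in one (0.00105) than in the real split (0.00141). Off-target action of the siRNA cannot be told apart from silencing, because the labels name 1 treatment against HSD17B14 and the deciding test, a second siRNA of another sequence, was not analysed here. The same limit holds for every difference between the groups described here, including the 71 called probe sets and the other gene lists.

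Genes in gene-dense regions tended to be lower. Over 8840 genes above the median signal, the log2 change had a Spearman rho of -0.19 with the number of protein-coding genes within 1 Mb, and medians went from 0.04 in the fifth with the fewest neighbours to -0.10 in the fifth with the most (genes are not independent replicates). All 9 pairs of arrays from opposite groups had a negative rho, with a median size of 0.142. Pairs of one group reached 0.115, or 0.814 of that median, so an array-to-array bias cannot be told apart from an effect of silencing. Gene length had a rho of 0.03 with the change.

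SPANXB1 rose, and so did CTCFL, another gene normally expressed in testis (2.06-fold, limma adjusted p = 0.0211), which raised the hypothesis of a joint rise of cancer-testis genes. Outside the SPANX copies, which may share probes with SPANXB1, 18 other such genes had a mean log2 level above 5 (SSX2IP and CTAGE genes, which share only a symbol stem, and SPANX were left out after their values were seen), and they were higher as a set, with 14 above 0, a mean of 0.24 ± 0.06 (SE over genes), camera p = 4.7e-05 and exact permutation p = 0.2 over the 10 splits. Of these, 9 are CT45A copies that may share probes. CT45A8 and CT45A9 had identical values (log2 change 0.55 each), so the gene-level mean, its SE and camera p count that measurement more than once. With 1 mean per family, 5 of 6 families were above 0, with a median of 0.06 (camera p = 0.158, exact permutation p = 0.3). With SPANX genes other than SPANXB1 counted, camera gave p = 5.6e-08 for 22 genes and p = 0.0268 for 7 families (exact permutation p = 0.1 each), but part of this restates the rise of SPANXB1. The 18 genes also had p under 0.05 in 3 of 9 other splits, with a lower camera p in one (3.9e-05) than in the real split, so a joint rise beyond SPANX remains open.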
